A study of Rattus norvegicus with 2 samples.

How the data were processed

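The series holds 2 two-colour arrays of an Agilent whole-genome rat design (014879). Per the labels, mRNA was isolated from lysed cell samples with magnetic beads, the cDNA made from it was amplified by a global PCR method, and equal amounts of each amplified cDNA were labelled. Wild-type cDNA was labelled with Cy3 and HIP cDNA with Cy5, per the labels, and extracts 1 and 3 shared array 1 while extracts 2 and 4 shared array 2. Dyes were not swapped, so genotype and dye cannot be told apart. The file headers place both arrays on 1 slide and in 1 scan, so no batch could be tested. PCR amplification can change the proportions of transcripts, and its effect was not measured here.

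Spots were quantified by the authors with Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited scanner output gives, for each spot and dye, the mean spot intensity and the median intensity of the local background as scanned, without normalization. It also gives a processed signal intensity which, per the file headers, was background-subtracted, spatially detrended and dye-normalized by a linear and lowess method. The log10 ratio of each spot is, per the file headers, the processed Cy5 signal over the processed Cy3 signal. The p-value of each spot's log ratio comes, per the file headers, from the software's error model for single arrays. The deposited table of the whole series has 36824 entries under 36716 probe names, and 36734 of them were matched to a gene probe. Of these, 32868 (89.5%) equalled the scanner's log10 ratio of the named array within 2e-05 on both arrays, so its scale is log10 and its direction is Cy5 over Cy3, without further centring. Of the 3866 unequal entries, 3689 were for transcripts with several probes, and how the authors combined those probes stays unknown. The genome build behind the array's probe positions is not given in the sources used here, and no coordinates are printed.

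The scanner intensities were analysed in R 4.3.3 with limma 3.58.1. Background was corrected with normexp (offset 50) on the mean spot and median background intensities of all spots. Ratios were normalized within each array by loess, with control spots at weight 0. The log2 ratio of Cy5 over Cy3 was taken from the deposited intensities in this way, so a positive value is higher in HIP. Control spots and spots with an outlier mark (173, 133, 128 and 119 gene spots in wild type 1, HIP 1, wild type 2 and HIP 2) were then left out, and replicate spots of a probe were averaged. A probe was kept if it was well above background on both arrays in at least 1 dye, which kept 33229 of 41012 gene probes (81.0%). Where a gene had several such probes, the one with the highest mean signal stood for it. This left 27867 genes, 13968 of them with a gene symbol.

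Gene names are those of the array's design, updated through a table of RefSeq genes of the GRCr8 assembly that was used for names only. Of the 41012 probes, 20094 were matched in this way, 10735 by their own transcript accession, 117 by another listed accession and 9242 by symbol or synonym. The array's name was kept for 19290 probes, and 1628 probes carried no gene name and were not tested.

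The log2 ratios were tested against 0 with lmFit and eBayes (two-sided, 1 residual degree of freedom per gene, prior degrees of freedom 1.69 and prior SD 0.689), with Benjamini-Hochberg adjustment at 0.05 over all genes tested. Counts of genes at least 2-fold apart on each array and the correlation of ratios between arrays were given without a test. The 27 gene lists, covering islet hormones, beta cell genes, exocrine, ductal, immune, vascular, stromal and neural markers, inflammation, stress, cell cycle and metabolism, were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and against 10000 random lists drawn from 20 bins of signal. For genes measured in 1 genotype alone, a bound was the mean normalized log2 level of the measured genotype over the higher of the other genotype's own level and the lowest signal well above background. Such bounds are open to dye bias because the dyes were not swapped. Percentile ranks of marker genes in each extract come from the scanner's processed signals, ranked among all 41012 gene probes.

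Named genes followed a rule. They were the 12 highest and 12 lowest mean log2 ratios among genes with a symbol that were well above background in both dyes of both arrays, taken first from genes past the test and, as none passed, from genes at least 2-fold apart on both arrays. They also included up to 5 genes per direction with the largest bound, up to 4 members of each list (the 2 largest mean ratios with 1 sign on both arrays and the 2 brightest), and a fixed set of islet, immune, ductal, stress and acinar genes. Some genes that the rule names are not reported here. The comparison, its test, the gene lists, this rule and all but 4 of the processing alternatives were chosen before the data were examined.

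The alternatives were no background subtraction, a normexp offset of 16, the scanner's processed signals and log ratio, median centring, no normalization, scaling between arrays, no filter or a stricter filter on dim probes, the mean of a gene's probes, each probe on its own, a trended or robust prior, the 4 channels without array pairing, the deposited table, the scanner's error model (p under 0.01 with a 2-fold ratio on both arrays), other thresholds, and each array alone. Filters relative to the signal of olfactory receptor probes (their 95th percentile), and an estimated correlation in camera under the strictest of them, were chosen after seeing the data. Values relative to the median of all genes had the median of the tested genes on each array subtracted, and this was also chosen after seeing the data. The test was tried on simulated data in which 200 of 27867 genes were changed. With the spread of these arrays 0 were recovered at log2 ratios of 1, 2 or 4. At a spread 4 times smaller 78.5% were recovered at a log2 ratio of 4, and at a spread 16 times smaller 86% were recovered at 1. The number of arrays limits the precision of the values.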

Results

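Gene expression was compared between HIP rats, which carry a transgene for human islet amyloid polypeptide (IAPP), the amyloid-forming peptide that beta cells release together with insulin, and nondiabetic wild-type rats. The series title names islet inflammation, proliferation of ductal cells and pancreatitis in type 2 diabetes as its subject. Amplified cDNA from 2 wild-type and 2 HIP extracts was hybridised in pairs to 2 two-colour whole-genome rat arrays. The wild-type extract was labelled with Cy3 and the HIP extract with Cy5 on both arrays, so each array gave 1 ratio of HIP to wild type for each gene and n = 2 throughout. The labels describe the material only as cell samples and do not name the tissue, and nothing in them says that the extracts came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

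Signal over background differed between the extracts. The median gene spot was 5.25 times its local background in wild type 1, 5.11 times in HIP 1, 2.91 times in wild type 2 and 5.09 times in HIP 2. The scanner software called 83.5%, 85.0%, 73.6% and 84.1% of the 43379 gene spots well above background in these extracts, and 0 gene spots were saturated. Of the 1115 spots for olfactory receptors, which are expressed mainly in the olfactory epithelium, 88.4%, 90.04%, 77.4% and 89.0% were also well above background, against 0% of the 153 negative control spots. A spot well above background was therefore not by itself taken as a sign that its gene was expressed.

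Among genes with a symbol that were well above background in both dyes of both arrays, the highest HIP to wild-type ratios included Ppp2r2d, a regulatory subunit of protein phosphatase 2A, with a mean log2 ratio of 4.70 ± 0.18 (SD, n = 2 arrays). Ppp1r3c, which targets protein phosphatase 1 to glycogen, followed at 4.63 ± 1.02, and Ndufab1, the mitochondrial acyl carrier protein, at 4.53 ± 1.58. Tfap2d (4.36 ± 1.33), Lama4 (4.30 ± 0.26), Chd1l (4.21 ± 1.24), Apc (4.14 ± 1.81), Cox6c (3.91 ± 1.63), Mrm1 (3.75 ± 0.63), Rbp4 (3.71 ± 0.34), the trypsinogen gene Prss3 (3.64 ± 1.33) and Camlg (3.63 ± 0.72) completed the 12 highest. The lowest ratio among such genes belonged to Fcf1, a factor of ribosome assembly, at -6.26 ± 0.88. M6pr, the cation-dependent mannose 6-phosphate receptor that sorts lysosomal enzymes, stood at -5.24 ± 0.68, and Vwa5a at -5.14 ± 1.26. Supt16h (-5.13 ± 0.81), Pdlim3 (-5.06 ± 2.94), Tpt1-ps2 (-4.95 ± 0.31), Pdcd6ip (-4.71 ± 1.00), Chd1 (-4.60 ± 0.74), the olfactory receptor Or8k1 (-4.58 ± 1.69), Tmem11 (-4.55 ± 0.94), Golga7 (-4.53 ± 0.64) and Acly (-4.52 ± 1.09), the enzyme that makes cytosolic acetyl-CoA, completed the 12 lowest. None of these 24 genes passed the test, and they are given as values.

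Of these 24 genes, 10 had another probe that passed the filter. For Fcf1 the second probe gave -5.55 on array 1 and -6.82 on array 2, close to the first. For the other 9, no further probe was at least 2-fold on both arrays in the direction of the named one. A second probe for Chd1 gave 3.02 and 4.49 against -4.08 and -5.12 for the brightest one, and 2 further probes for Lama4 gave -1.44 and -3.27, and 0.08 and 0.31. Of the 24, 8 had mean log2 ratios over 1.5 times smaller in the authors' deposited table, with a change of sign for Lama4: Lama4 (-0.07), Ppp1r3c (0.27), Chd1l (2.66), Chd1 (-0.01), Golga7 (-0.37), M6pr (-0.61), Vwa5a (-1.74) and Pdcd6ip (-1.86). The others lay between 3.67 and 5.66 or between -6.87 and -4.77 there.

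By limma with Benjamini-Hochberg adjustment, 0 of 27867 genes were higher and 0 were lower in HIP at an adjusted p of 0.05, and the smallest adjusted p was 0.933. At an unadjusted threshold of 0.05, 914 genes passed (493 higher and 421 lower), against 1393 expected by chance. The counts were also 0 with a trended prior (862 genes at the unadjusted threshold), with a robust prior (836) and with the 4 channels fitted as separate samples (1095). The error model of the scanner software, which describes spots on 1 array and not differences between samples, gave 1468 genes higher and 1288 lower on both arrays, and 2769 in opposite directions. With 2 ratios, an exact sign-flip test of a single gene cannot give a p below 0.5. In simulated data with the spread of these arrays, limma recovered 0 of 200 genes changed by a log2 ratio of 4, and with a spread 4 times smaller it recovered 157 of 200 on the same 2 arrays.

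After loess, large ratios were about as often opposite as alike on the arrays. Ratios of at least 2-fold on both arrays were found for 2990 genes, of which 750 were higher in HIP on both, 689 were lower on both and 1551 were higher on one array and lower on the other, so 48.1% went the same way. With the ratios centred on their median in place of the loess correction, 2530 went the same way and 1575 opposite ways, and without normalization, which shifts all genes upward, 7982 and 1430. If the arrays had been independent, 606 genes higher and 619 lower on both would be expected, and also 521 higher on array 1 and lower on array 2 (624 found) and 720 the other way round (927 found). Of genes 2-fold or more apart on both arrays in the same direction, 52.1% were higher in HIP. With median centring this share was 84.9%, and without normalization it was 98.0%. Those settings put the median log2 ratio of all genes at 0.18 and 0.27, and at 0.81 and 1.22, on arrays 1 and 2, against 0.03 and 0.02 after loess. Those 2 settings differ from each other by 1 constant per array and from the loess values also by a trend with brightness. Directions below are those of the loess values, and where median centring turns the sign of a gene's mean relative to the median of all genes, that relative mean is given. Across genes, which are not independent replicates, the ratios of the arrays had a Pearson r of -0.011 and a Spearman rho of -0.009. The ratios spread as widely on each array, with SDs of 1.36 and 1.41.

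**Figure D1:**
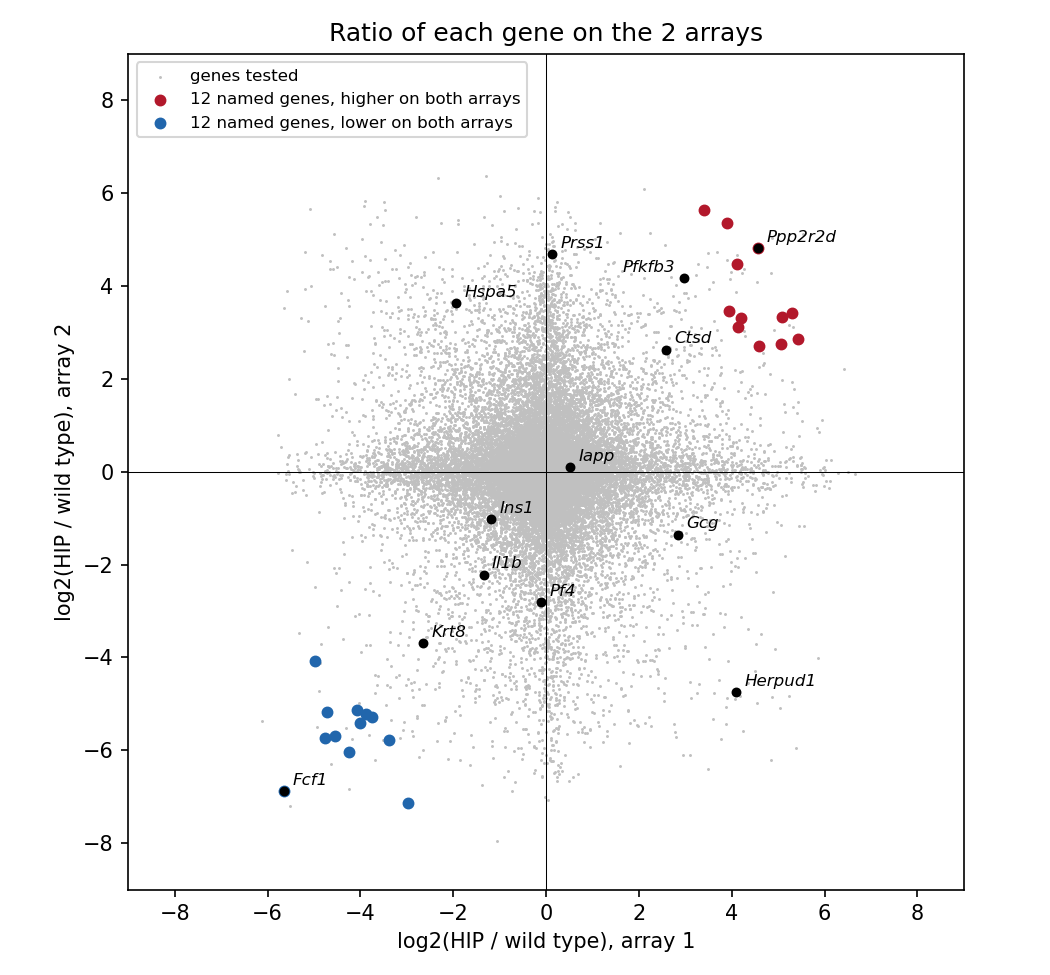
The log2 ratio of HIP to wild type on array 1 (horizontal axis) is plotted against that on array 2 (vertical axis), with 1 grey point for each of the 27867 genes tested, the 12 highest named genes in red, the 12 lowest in blue, and other named genes as black labelled points. The cloud has no slope (r = -0.011), Herpud1 lies at 4.10 and -4.75, and Fcf1 lies at -5.64 and -6.88; relative to the median of all genes, the mean of Herpud1 turns from -0.35 to 0.24 with median centring.

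Of the 27 gene lists fixed before the data were examined, 0 were called higher and 0 lower by camera with a preset correlation of 0.01, and the smallest adjusted p was 0.727. With an estimated correlation the smallest adjusted p was 0.898, and against 10000 random lists matched on signal it was 0.671. In each of the 27 lists, 0 members passed over all genes tested and 0 passed when adjusted over the list alone. The lists held 561 measured genes, of which 293 had the same sign on both arrays, 38 were 2-fold apart the same way on both and 32 were 2-fold apart in opposite directions. The medians of 9 lists differed in sign between the arrays. Relative to the median of all genes, the median of 7 lists took the other sign with median centring. The same 7 did so without normalization by construction, as those 2 settings differ by 1 constant per array. As none passed the test, no list is given a direction here. A shift of 1 log2 unit in all 25 measured chemokines was called in simulated data with the spread of these arrays (camera adjusted p = 0.000145). The simulated genes varied independently of each other, and only the preset correlation was tried. That result therefore does not show that such a shift would be found in these lists.

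Among islet hormones and granule proteins, 6 of 19 measured genes were higher in HIP on both arrays, 6 were lower on both and 7 differed in direction. Both rat insulin genes were lower, Ins1 at -1.10 ± 0.12 and Ins2 at -0.94 ± 0.14 (SD, n = 2 arrays). With median centring they were -0.46 and -0.23 relative to the median of all genes. Before any dye correction Ins1 was 0.39 and 0.72 on arrays 1 and 2, against medians of 1.5 and 1.73 for the 200 genes of closest signal, and Ins2 was 0.69 and 0.88 against 1.62 and 1.83. Ptprn2 stood at -2.65 ± 1.76 and Pam, which amidates peptide hormones, at 1.82 ± 0.19, while a second probe for Ptprn2 averaged 0.91. Gcg, the glucagon gene, was 2.84 on array 1 and -1.35 on array 2. Iapp, the rat gene of the peptide, was 0.51 and 0.10, and Sst, the somatostatin gene, was 0.13 and 0.09, but relative to the median of all genes their means were -0.10 and -0.46 with median centring. With the scanner's processed ratios their means were 1.12 and 0.58. Of the transcription factors and glucose sensors of beta cells, 5 of 20 were higher on both arrays, 4 were lower on both and 11 differed. The insulin activator Mafa was -1.37 ± 0.54. Hnf4a was 0.04 ± 0.04, with the opposite sign (-0.10) in the deposited table, and Kcnj11 was 1.78 and -1.86, with a mean of 0.60 relative to the median of all genes with median centring. Of genes that mature beta cells keep low or regain on dedifferentiation, 6 of 19 were higher on both, 4 were lower on both and 9 differed. Rest, a repressor of neuronal genes, was 1.57 ± 0.33 and its second probe averaged -0.92, and Oat was 4.57 and 0.23, with -0.08 and -0.26 from its other probe.

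Of the acinar enzymes, 10 of 25 measured genes were higher on both arrays, 7 were lower on both and 8 differed. Prss3 was 4.59 and 2.70, Prss1 was 0.13 and 4.68, Amy2 was 0.72 and 0.00, and Rnase1 was -0.19 and -0.14, with a mean of 0.54 relative to the median of all genes with median centring. Cpa1 was not tested because its spot on array 1 was an outlier, and its ratio on array 2 was 0.18. The ductal epithelium list, which had the smallest p of the 27 (adjusted p = 0.727), held 4 genes higher on both arrays, 9 lower on both and 11 that differed, of 24 measured. Its median was -0.29, or -0.32 relative to the median of all genes and -0.27 so with median centring. Krt8, a keratin of simple epithelia, was -3.17 ± 0.74, its partner Krt18 was -2.86 and 1.30, with -2.18 and -1.45 from its other probe, and Krt20 was -1.32 ± 0.25. The ductal markers Krt19 (-0.88 and 0.13), Sox9 (0.02 and 0.74) and Cftr (0.18 and 0.48) had smaller ratios, and other probes for Sox9 and Cftr averaged below 0. Muc6 was 0.38 and 3.67, with -0.13 and -0.16 from its other probe. Of the regenerating islet-derived family, 2 of 3 measured genes were higher on both and 1 differed, with Reg3a at 0.52 ± 0.15 and Reg3g at 0.13 and 0.05.

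The chemokine list had 6 of 25 genes higher on both arrays, 9 lower on both and 10 that differed. Ccl22 was 2.01 ± 0.05, with -0.91 from its other probe, and Ccl3 was -1.89 ± 0.06. Ccl21 was -1.47 ± 0.37 and Ccl19 was 0.36 and -0.25. Cxcl10 was 0.16 and 0.04, with a mean of -0.46 relative to the median of all genes with median centring but 0.69 with the scanner's processed ratios. Ccl2 was -0.02 and -0.08, and Pf4 was -0.11 and -2.81. Cxcl1, a neutrophil attractant, did not pass the filter because it was not well above background in either dye on array 2. Its processed signal was 66.6 in wild type 1 and 7352 in HIP 1, but 30.2 in wild type 2 and 39.1 in HIP 2. Among inflammatory cytokines and growth factors, 5 of 24 were higher on both arrays, 10 were lower on both and 9 differed. Il1b was -1.78 ± 0.61 (its other probe averaged -0.07), Tnf was -0.20 and -0.55, and Tgfb3 was -4.86 and -0.08. NF-kB target genes were higher on both arrays in 6 of 18 cases, lower on both in 2 and different in 10. Icam1 was 1.04 ± 0.71, Nfkb1 was 0.25 and 1.68 (2.21 and 0.08 from its other probe), and Nfkbiz was 0.72 ± 0.81. Interferon-stimulated genes were higher on both in 5 of 23, lower on both in 2 and different in 16. Irgm was 1.47 ± 0.83 and Stat2 was 0.01 and 1.69. Antigen presentation genes were higher on both in 3 of 16, lower on both in 5 and different in 8, with Ciita at 0.26 and 2.44, RT1-Da at -1.59 and -0.24 (0.06 and 0.05 from its other probe) and RT1-A2 at 1.34 and -1.28, or -0.14 and -1.19 from its other probe, and the mean of the first was 0.53 relative to the median of all genes with median centring.

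Genes of ER stress and the unfolded protein response were higher on both arrays in 4 of 28 cases, lower on both in 9 and different in 15. Atf6, a sensor of unfolded protein, was -1.79 ± 0.80 and the chaperone Canx was -1.25 ± 0.25. Hspa5 (BiP) was -1.94 and 3.64, Herpud1 was 4.10 and -4.75, and Ddit3 (CHOP) was -0.70 and -0.13. Apoptosis genes and p53 targets were higher on both in 6 of 26, lower on both in 5 and different in 15. Bcl2 was 1.80 ± 1.26 (2.69 and 0.91 on arrays 1 and 2), but 0.26 and 3.24 from its other probe. Sesn2 was 2.25 and 0.35, and Cdkn1a was -0.75 and 0.39, or -2.49 and 0.50 from its other probe. The mean of the first Cdkn1a probe was 0.29 relative to the median of all genes with median centring. Proliferation genes were higher on both in 6 of 32, lower on both in 11 and different in 15. Cenpf, a kinetochore protein, was -3.79 ± 1.28 but -0.08 from its other probe, and Ccne1 was -0.14 and -3.73, with 0.62 and 0.89 from its other probe, while Mki67 was 0.70 ± 0.36 and Cdc20 was 0.83 ± 0.39. Heat shock proteins were higher on both in 6 of 18, lower on both in 7 and different in 5. Hsp90ab1 was -1.60 ± 0.01, with -2.40 from its other probe, and Hspa4 was 0.77 ± 0.05. Hspa1a was -3.76 and -0.82, with 3.30 and 0.07 from its other probe and a mean of 1.78 in the deposited table. Hspa8 was -2.13 ± 1.19, with the opposite sign in the deposited table (0.44) and as the mean of its probes (0.56). Oxidative stress genes were higher on both in 3 of 19, lower on both in 3 and different in 13, with Prdx2 at -2.03 ± 0.49 and Prdx1 at 1.28 ± 1.16. Genes of autophagy and the lysosome were higher on both in 11 of 27, lower on both in 5 and different in 11. The lysosomal protease gene Ctsd was 2.60 ± 0.04, and Cd63 was 0.37 and 3.59. Immediate early genes were higher on both in 4 of 21, lower on both in 2 and different in 15, with Jund at 0.73 ± 0.34 (0.31 and -0.50 from its other probe) and Nr4a3 at 1.97 and 0.16, or a mean of 2.74 with the scanner's processed ratios.

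Genes of hypoxia and glycolysis had 10 of 29 members higher on both arrays, 8 lower on both and 11 that differed. The highest were Pfkl, the liver phosphofructokinase, at 3.62 ± 2.38 and Pfkfb3, which makes the activator of phosphofructokinase, at 3.57 ± 0.85. Pgam1 was -1.73 ± 0.54 (-2.11 and -1.35 on arrays 1 and 2), with -2.95 and -0.15 from its other probe. The mitochondrial respiratory chain had 9 of 26 genes higher on both, 7 lower on both and 10 that differed. Cox6c was 3.91 ± 1.63 and Atp5pd was -1.89 ± 1.42. Of the housekeeping genes, 8 of 23 were higher on both, 6 were lower on both and 9 differed. Pgk1 was 3.16 ± 1.43 and Tubb5 was -3.26 ± 1.69. Gapdh was 0.43 ± 0.08, but -0.14 in the deposited table and -0.02 as the mean of its probes.

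No list of markers of other cell types passed the test. Macrophage and myeloid markers were higher on both arrays in 4 of 24, lower on both in 9 and different in 11, with Mpo at -4.42 and -0.14, Aif1 at 1.38 ± 0.55, Laptm5 at 2.09 and 0.24, and Cd68 at 0.16 and -0.09, with a mean of -0.38 relative to the median of all genes with median centring. Lymphocyte markers were higher on both in 3 of 23, lower on both in 4 and different in 16, with Gzma at -1.18 ± 0.11 and Cd8a at -1.39 ± 0.58. The pan-leukocyte gene Ptprc was 1.75 and 0.14, and its other probe averaged -1.66. Endothelial markers were higher on both in 7 of 23, lower on both in 5 and different in 11. Sox18 was 1.86 ± 0.42, with -0.54 and 1.13 from its other probe, Podxl was -2.73 ± 1.74 and Pecam1 was 0.22 ± 0.09, or -0.27 relative to the median of all genes with median centring and 1.31 with the scanner's processed ratios. Stellate cell and fibroblast markers were higher on both in 2 of 21, lower on both in 9 and different in 10. Sparc was -1.63 ± 0.85, Col5a1 was -0.10 and -2.48 (-1.57 and -2.49 from its other probe), and Col1a1 was 0.37 and -0.16. Schwann and neural markers were higher on both in 3 of 13, lower on both in 2 and different in 8, with Prph at -2.11 ± 0.45 and Mbp at 0.30 and 2.14 (-0.30 and 0.07 from its other probe). Red blood cell genes were higher on both in 3 of 7, lower on both in 2 and different in 2, with Ahsp at -1.58 ± 1.75 and Epb42 at -2.84 and -0.24.

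The median and the mean of the gene ratios differed in sign in 8 lists. These were beta cell identity, ER stress, apoptosis, the respiratory chain, lymphocyte markers, heat shock proteins, red blood cell genes and housekeeping genes. In 3 of them, beta cell identity (mean 0.02), the respiratory chain (mean 0.03) and housekeeping genes (mean -0.05), the mean also differed in sign from the direction given by camera. Of the 145 named genes, 55 had several probes past the filter, and in 33 of these the probes differed in sign. Wild type was not well above background on either array for Cxcl10 and Nr4a3, nor on 1 of the arrays for Iapp, Sst, Rest, Krt19 and Pecam1, and HIP was not on 1 array for Cenpf. The ratios of these 8 genes rest on a dim signal, and with the scanner's processed ratios the means of Rest and Krt19 were 3.48 and -0.74. For Cenpf the mean was -0.10 there, but it came from the other probe, which was the brighter by the processed signals. Of 143 named genes, the mean of 23 changed sign or moved by over 1.5 times with the processed ratios, as did 57 of 141 in the deposited table.

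**Figure D2:**
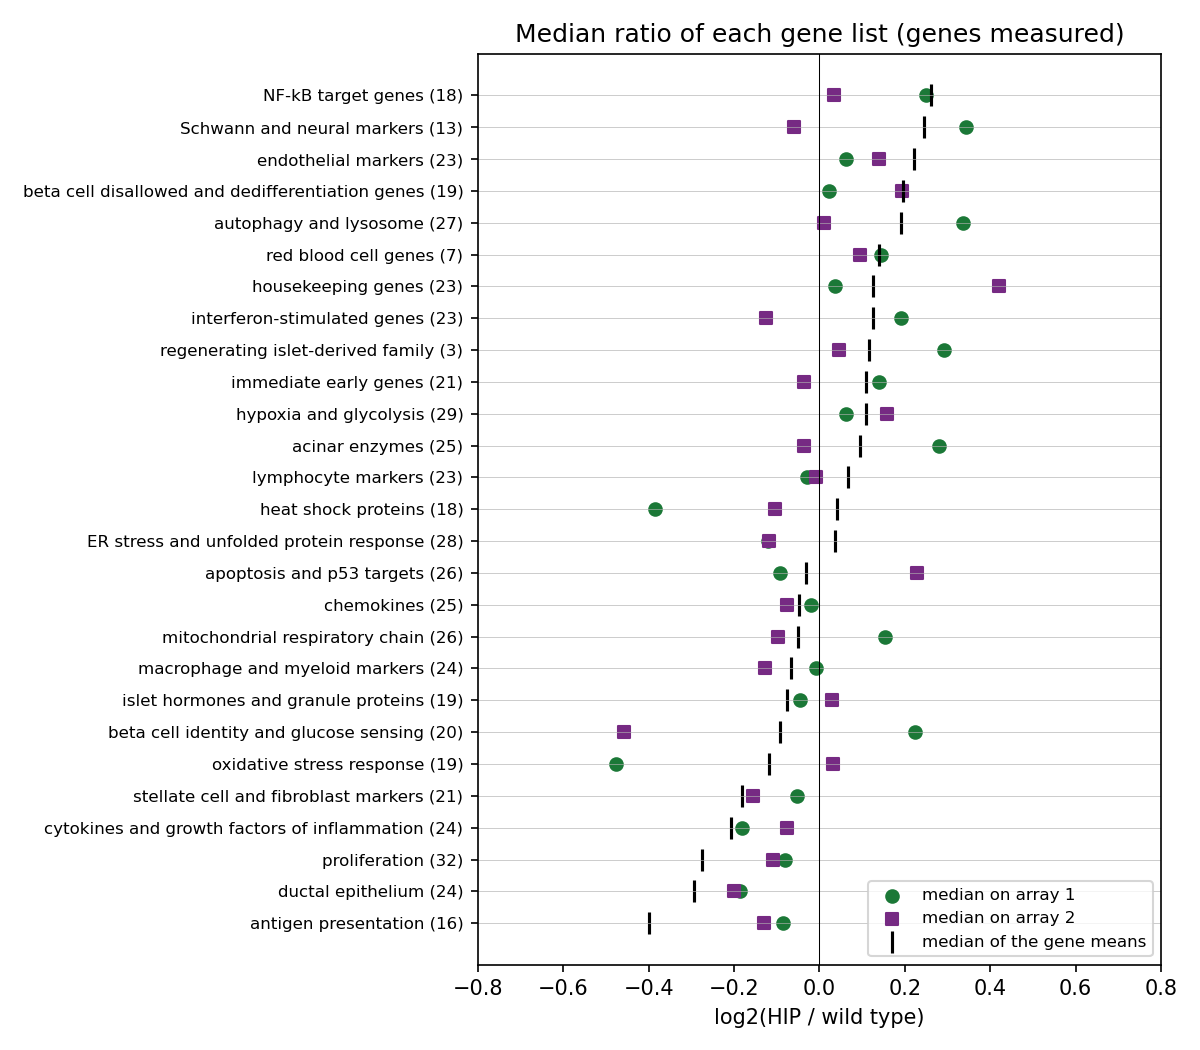
For each of the 27 gene lists (vertical axis, with the number of genes measured), the median log2 ratio of HIP to wild type (horizontal axis) is shown for array 1 (circles), array 2 (squares) and the means of both arrays (bars). The medians of 9 lists differ in sign between the arrays, 0 lists passed the test, and relative to the median of all genes the median turns in 7 lists with median centring.

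Levels of the marker genes were ranked within each extract. Ins2 lay at percentiles 99.6, 98.4, 99.2 and 98.5 of all gene probes in wild type 1, HIP 1, wild type 2 and HIP 2. The acinar gene Rnase1 lay between 99.04 and 99.3 and the myeloid gene Laptm5 between 96.7 and 99.9. Iapp lay between 20.9 and 34.0 and Sst between 17.4 and 21.7. Ranks of different probes also carry differences between probes and were not compared with each other. Across the kept probes, the log2 processed signals of extracts on the same array correlated at 0.755 and 0.750. Those of the wild-type extracts correlated at 0.719 and those of the HIP extracts at 0.723. Extracts that shared neither array nor genotype correlated at 0.733 (wild type 1 with HIP 2) and 0.702 (HIP 1 with wild type 2).

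Some genes were well above background in only one genotype. In HIP alone 620 genes were, led by Susd1 (12.9-fold higher in HIP), Vwa3a (5.90), Pus3 (5.15), Pacc1 (4.62) and Cavin4 (3.51). In wild type alone 50 genes were, led by Lrrc18 (2.55-fold lower in HIP), Cisd1 (2.34), Cdc25a (1.86), Or2a5 (1.67) and Sar1b (1.48). For each gene named here the other genotype's own level set the value. The folds are therefore measured ratios of mean levels over 2 arrays and not assured minimums. None of these genes passed the test (limma adjusted p = 0.933). The lower signal over background of wild type 2 and the fixed dye of each genotype bear on these counts.

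The authors' deposited table held 1 log10 ratio column for each array. Its values correlated with the log2 ratios of the same arrays at 0.949 and 0.936 across genes, and its columns had medians of 0.011 and 0. The correlation between its columns was -0.011 across all entries.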

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

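All tests of explanations in this part were chosen after the result was seen.

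Control spots outside the comparison gave signal above the negative controls, of which 0% were well above background. Of the 222 spots with AT control probes, 85.6% in wild type 1, 85.6% in HIP 1, 74.8% in wild type 2 and 80.2% in HIP 2 were well above background. Of the 320 spots with E1A spike-in probes, 99.1% in wild type 1, 100% in HIP 1, 96.9% in wild type 2 and 100% in HIP 2 were. Per the file headers, the slope of observed on nominal spike-in log ratios was -0.12 on array 1 and -0.15 on array 2. The headers' correlation field held 0.10 and 0.07. A correlation has the sign of the slope, so these values are not a signed correlation. A slope of 1 would mean that observed and nominal ratios matched, so the observed ratios of these spots did not follow the nominal ones. Whether spike-in RNA was added to these samples was not established here. If none was, the nominal ratios do not apply and the slope does not bear on the accuracy of the gene ratios.

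The log2 ratios of the arrays did not correlate across the 27867 genes (r = -0.011). A swapped genotype label on 1 array cannot be told apart from none, because turning the sign of array 2 only turned the sign of r, to 0.01078, which is as close to 0. Noise or non-specific signal at single probes may account for much of the spread, since 2 probes of a gene on the same array correlated at only 0.1505 and 0.114 over 3274 genes. Spot noise was small for the 263 probes with replicate spots, whose log2 ratios by the scanner had median SDs of 0.109 and 0.125. Their brightness was not compared with that of the paired probes, so spot noise at dim probes is not excluded. Differences between the pairs of samples carried by whole genes stay open, because where both probes were bright (249 genes) they correlated at 0.448 and 0.2535 within an array and at 0.082 across arrays, and a genotype effect smaller than either cannot be told apart from none.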

How the results depend on the processing

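The 3 filters relative to olfactory receptor signal, and the estimated correlation used with 1 of them, were chosen after seeing the data. The 0 genes and 0 lists called kept under every other setting tested with limma or camera, the fit without array pairing included (smallest adjusted p for genes 0.284 without normalization and 0.717 to 0.965 under the rest). The block of paired extracts on an array is the main design, and leaving the pairing out also called 0 genes (adjusted p = 0.952). Counts at least 2-fold higher and lower on both arrays were 1601 and 1308 with the scanner's processed ratios (r = 0.0084), 2148 and 382 with median centring (r = 0.040), 7825 and 157 without normalization (r = 0.040), and 1509 and 1205 in the deposited table (r = 0.012). They were 1592 and 1496 at 1.5-fold and 171 and 194 at 4-fold, by construction. A single array gave 3929 to 4298 higher and 3694 to 4667 lower. The scanner's error model called 1468 genes higher and 1288 lower. Among 1869 genes above the olfactory receptor level in both extracts of a genotype, limma called 7 higher and 15 lower, with 65 and 96 at 2-fold and r = 0.31. Among as many genes brightest by the mean of the 4 extracts it called 0, with 40 and 43 and r = -0.069. Among 1130 genes above that level in all 4 extracts it called 0, with 7 and 12, r = -0.091, and 1 list lower, islet hormones (Ins1, Ins2 and Scg5), which an estimated correlation did not call (adjusted p = 0.373). Fewer genes were tested under these filters, although the 1869 brightest genes gave 0 calls, and only 8, 8 and 2 lists kept 3 members. The gene calls under the first filter and the list call under the last are taken up below. The cause of the other changes was not tested. With scalings taken relative to the median of all genes, 30 of 143 named genes and the medians of 16 of 27 lists changed sign under at least 1 setting of both arrays. Signal over background, lowest in wild type 2 at 2.91, limits what a ratio of dim probes can show.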

Other observations

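All tests of explanations in this part, and the choice of the genes it names, followed after the values were seen.

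The 500 brightest genes of the arrays held few large differences that both arrays shared. Retn, which encodes the adipocyte hormone resistin, was -1.50 and -1.09 on arrays 1 and 2, and Ticrr, a regulator of replication origins, was -1.73 and -1.48. They were among 6 genes at least 2-fold lower in HIP on both arrays, and Tnk1 (1.17 and 2.10) was among 2 that were higher. Another 33 were 2-fold apart in opposite directions. Tpm3, a tropomyosin, was 1.56 and -1.39, Gosr1, a Golgi SNARE, was 1.29 and -1.92, Rab6a was -1.57 and 1.54, and the ribosomal protein gene Rpl35a was -1.60 and 1.65. Across these 500 genes, which are not independent replicates, r was -0.173. All these are loess values, and the genes of this paragraph were not followed under the other scalings. The mean of Ins2, also a bright gene, moved from -0.94 to -0.01 with median centring.

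Among 3274 genes with several probes past the filter, 20 had at least 2 probes that were 2-fold apart the same way on both arrays, and 19 had at least 2 probes that were 2-fold apart in opposite directions. The 11 higher in HIP included Mat2a, which makes S-adenosylmethionine (1.15 and 5.37, and 2.06 and 4.80), Mrpl17 (2.93 and 2.08, and 3.56 and 2.74) and Btf3, whose remaining probe was -1.54 and 4.59. The 9 lower included Fcf1, Hsp90ab1 (-1.59 and -1.61, and -1.59 and -3.20) and Golt1b (-4.24 and -1.38, and -2.86 and -5.68). Hspd1, also among them, had another probe at 2.56 and 1.44. Ratios in opposite directions were given by 2 probes for Rheb, Rpsa and Cbx3. A transcript without a gene symbol gave them with several probes. Among these were 1.68 and -2.49, and 1.34 and -2.88, both above the olfactory receptor level in all 4 extracts. It is also among the 33 of the 500 brightest genes that went in opposite directions.

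Restricting the test to genes above the olfactory receptor level in both extracts of at least 1 genotype gave 22 calls, including Ppp2r2d, Lama4 and Mrm1 higher and Fcf1, Pdcd6ip and Acly lower. That filter favours genes that are bright in the same genotype on both arrays, and this selection may account for the calls. The mirrored filter, bright in 1 extract of each genotype with the sign of array 2 turned, gave 37 calls, with an r of 0.444 against 0.311. A genotype difference in genes well above non-specific signal cannot be told apart from the selection, because only 1 of the 22 called genes was among as many genes chosen by their mean over the 4 extracts, where 0 were called.

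Insulin signal was about 2-fold lower in HIP on both arrays, with a mean log2 ratio of -1.02 for Ins1 and Ins2. Of the 200 genes closest to Ins1 in signal, 5 were on both arrays as low as its higher ratio. For Ins2 it was 8 of 200. In each case 1 gene was as far above 0 on both arrays. The brightness-dependent dye correction cannot be told apart from a difference in insulin. With median centring in its place the mean of Ins1 and Ins2 was -0.1206 (-0.35 relative to the median of all genes). Without normalization Ins1 was 0.56 and Ins2 was 0.78, as means of both arrays. Relative to genes of like signal, the mean without normalization was -0.998. That comparison also takes out the trend with brightness, as loess does, so it cannot decide. A lower share of beta cells in the HIP extracts stays open and cannot be told apart here, since the 17 other granule genes had a median of 0.1078 with an SD of 1.13 and went both ways. Among genes above the olfactory receptor level in all 4 extracts, camera called the islet list lower at its preset correlation (adjusted p = 0.0053) but not at an estimated one (0.373). The call rests on 3 of 19 members, Ins1, Ins2 and Scg5, and Scg5 had a mean of -0.69 but 0.22 from its other probe, and -0.0017 relative to the median of all genes with median centring.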
